A study of Mus musculus with 7 samples.

How the data were processed

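The libraries came from Kupffer cells, the resident macrophages of the liver, sorted from untreated 8-week-old male C57BL/6 mice. Per the labels' protocols, livers were perfused and digested with collagenase, and cells were sorted by flow cytometry. About 10000 cells per sample entered a bulk version of MARS-Seq, a method that tags the 3′ end of polyadenylated RNA and marks each molecule with a unique molecular identifier (UMI). The labels place 4 samples in a control group (mice with loxP-flanked Commd10 alleles and no Cre) and 3 in a Commd10-deficient group (the same alleles with Cre expressed from the Clec4f locus). Sample titles split the controls into 2 numbered sets of 2 samples each, called control set 1 (replicates 1 and 2) and control set 2 (replicates 3 and 4) here. Replicate numbers follow the order of the records and pair no samples.

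The authors deposited a table with 10550 gene symbols and a raw count per gene and sample under a heading for raw counts, per the file headers, and the UMI correction is given by the table's name. The authors also deposited a normalized signal per gene and sample in the same table, under a heading for normalized counts, per the file headers. From the values, each normalized column equals the raw column divided by a single factor per sample, up to rounding, so it was used only for that check. Every listed gene has at least 6 counts in some sample. Per the submitters' processing notes, cutadapt, HTSeq and DESeq2 were used with genome build mm10. Their versions and settings, the aligner and the treatment of strand and of reads shared between similar genes are not given in the sources used here. Library totals ran from 105462 to 4270240 counts, so a floor of 3 counts is 28.4 CPM in the shallowest library and 0.703 CPM in the deepest, and 7138 genes were not tested for low counts. The table lists 0 mitochondrially encoded genes. The number of columns with per-sample values that could not be matched to a sample was 0.

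Raw counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM library factors, robust empirical Bayes shrinkage and the default expression filter on the 2 genotype groups. Library sizes were the totals of the table. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05 with no minimum fold. Fold changes are Commd10-deficient minus control on the log2 scale, with the standard error derived from the F statistic. A second model with 3 levels (control set 1, control set 2, Commd10-deficient) gave the contrasts with each control set and between the control sets. Commd10 did not pass the expression filter and was added back to the tested genes in a separate fit. CPM values are counts scaled to the table total and the TMM factor, on the usual CPM scale, except those of Commd10 and of genes at 0, which were divided by the total alone. Intervals for the level of Commd10 are exact Poisson at 95%, and those for its pooled ratios come from an exact comparison of Poisson rates. For genes at 0, a floor of 3 counts was set on the total of the library, or on the pooled total of the Commd10-deficient libraries where a fold is given.

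Altogether 31 gene lists (cell types, pathways, complexes and quality measures) were tested with camera at a preset correlation between genes of 0.01, where at least 3 members were tested, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, and fry, both from limma 3.58.1, were run beside it. Fry asks whether the members of a list change, and not whether they change more than other genes. The lists are Kupffer cell identity, sort gate, pan-macrophage, monocyte, monocyte-derived and lipid-associated macrophage, MHC class II presentation, neutrophil, liver sinusoidal endothelial cell, hepatocyte, hepatic stellate cell and fibroblast, T and NK cell, B and plasma cell, dendritic cell, platelet and red cell, COMMD and partner complexes, lysosome, autophagy, efferocytosis and scavenger receptors, apoptosis and p53 targets, inflammasome and pyroptosis, cell cycle, NF-kB and inflammatory cytokines, interferon response, dissociation and immediate early genes, iron and heme handling, cholesterol synthesis and uptake, LXR targets, BMP, TGF-beta and Notch signal genes, complement, unfolded protein and integrated stress response, and mitochondrially encoded transcripts.

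The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The genes named are Commd10 in every sample, the genes of the sort gate and, among called genes with a mean of at least 10 CPM, no overlap between groups and a symbol that is not a Gm number, a Rik clone or an LOC name, the 12 with the largest fold change in each direction. Up to 4 tested members with the smallest p were also taken from each list, whether or not they passed. Genes named outside this rule are stated to have been chosen after their values were seen. Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no filter, a filter of at least 10 counts in at least 3 samples, each control set alone, the model with 3 levels, no robust shrinkage, each sample left out in turn and a minimum absolute log2 fold change of 1. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

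Chosen after seeing the data were an offset per library for GC content and transcript length (loess, span 0.5), that offset with control set 2 alone, and binomial thinning of all libraries to the lowest total in 10 random draws. Transcript length and GC content came from GENCODE release M21 on GRCm38, the same assembly as mm10. It held 10167 of the 10550 symbols (96.4%), and 97.0% of the tested genes. The tests were tried on simulated data drawn from the means, dispersion and library sizes of the 3412 tested genes, with 200 genes changed. Over 3 simulated runs, 14.3% of genes changed by 1 log2 unit and 72% of those changed by 2 log2 units were recovered, and 6.16% of calls were false. The simulated libraries held no shift between groups of libraries like the difference found between the control sets. The share of false calls therefore applies only where such a shift is absent. Pairs of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom from 1.64 to 16.4, so no library was treated as a copy of another. The lowest was between Commd10-deficient replicates 1 and 2, against 3.32 for each of them with replicate 3. Such a spread can also be technical, so these values do not show that the libraries came from separate animals.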

Results

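Kupffer cells from steady-state livers were profiled by 3′ UMI sequencing to compare cells labelled Commd10-deficient, in which Commd10 was targeted through Cre at the Clec4f locus, with control cells that the series description gives as littermates. Commd10 encodes a member of the COMMD protein family, whose members act with partner complexes in sorting of membrane cargo. The series title poses the question of whether COMMD10 is needed to maintain these cells at homeostasis. There were 4 control and 3 Commd10-deficient libraries. Control set 1 was much deeper than the rest, with 4270240 and 3207144 counts. Control set 2 held 230942 and 267553 counts, and the Commd10-deficient libraries held 116458, 105462 and 124016. Genes with at least 1 count numbered 10533 and 10473 in control set 1, 8089 and 8231 in control set 2, and 7527, 7456 and 7602 in the Commd10-deficient libraries. A floor of 3 counts corresponded to 0.703 CPM in the deepest library and 28.4 CPM in the shallowest. The labels do not state that each library came from a separate animal, so p-values measure the spread between these libraries, which may be technical. Control mice carried no Cre, so any effect of Cre or of the modified Clec4f allele goes with the genotype.

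**Figure D1:**
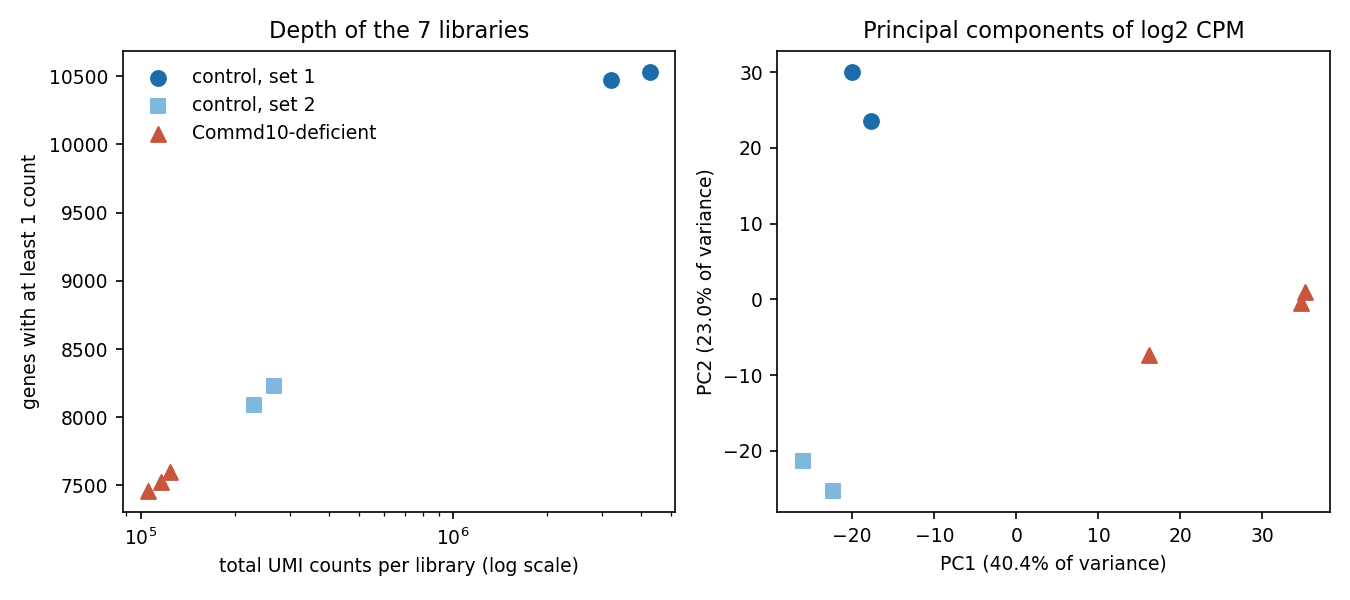
Depth and principal components of the 7 libraries. Left, total UMI counts per library on a log axis against the number of genes with at least 1 count, and right, the first and second principal components of log2 CPM over the tested genes, each point a library. The first component (40.4% of the variance) parts the Commd10-deficient libraries from both control sets, with Commd10-deficient replicate 3 (16.2) nearer the controls than replicates 1 and 2 (34.7 and 35.1), and the second (23%) parts the control sets from each other.

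Commd10 itself, on chromosome 18 from 46958816 to 47234284 on the plus strand (mm10), was sparsely counted in every shallow library. Counts were 167 and 130 in control replicates 1 and 2, and 7 and 1 in control replicates 3 and 4. In Commd10-deficient replicates 1, 2 and 3 they were 0, 4 and 2. In CPM these are 39.1, 40.5, 30.3 and 3.74 in the controls and 0, 37.9 and 16.1 in the Commd10-deficient libraries. The count of 0 allows up to 31.7 CPM (exact 95% interval), and the intervals of the other Commd10-deficient libraries run from 10.3 to 97.1 CPM and from 1.95 to 58.3 CPM. Over pooled counts, the Commd10-deficient libraries held 0.437 times the level of control set 1 (exact 95% interval 0.159 to 0.962, counting error only) and 1.08 times that of control set 2 (0.309 to 3.55). In edgeR the log2 fold change was -0.78 (SE 0.94, adjusted p = 0.66), so a difference was not detectable at this depth. With control set 2 alone the estimate was 0.0037. The labels do not give the deleted exons, and a 3′ tag that lies outside them would be counted in deleted cells too, so these counts do not check the genotype labels.

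In Commd10-deficient Kupffer cells, 206 of 3412 tested genes changed, 118 higher and 88 lower. The largest rises were in Anp32e, a histone chaperone (log2 fold change 3.84, SE 0.84), Gmfb, an actin regulator (3.46, SE 0.78), Tmed5, a cargo receptor of the early secretory pathway (3.29, SE 0.82), and Cap1, an actin-binding protein (3.21, SE 0.53). Some of these rest on few counts. Anp32e held 9, 8 and 6 in the Commd10-deficient libraries and 1 and 1 in control set 2. Gmfb held 11, 12 and 11 against 3 and 6, and Tmed5 16, 9 and 11 against 5 and 9. Cap1, on chromosome 4 from 122859047 to 122886056, went from 37.2 ± 23.4 CPM in controls (SD, n = 4) to 280 ± 81.4 CPM (SD, n = 3), and was 2.30 higher than control set 2 alone on the log2 scale. Lair1, an inhibitory collagen receptor, rose from 18.1 ± 6.48 to 133 ± 37.3 CPM (log2 fold change 2.91, and 2.76 against control set 2). Clec7a, the beta-glucan receptor Dectin-1, rose from 81.5 ± 54.7 to 434 ± 84.3 CPM (2.55, and 1.84 against control set 2, adjusted p = 0.154). Pck1, which encodes the cytosolic gluconeogenic enzyme PEPCK, rose by 2.93 (3.20 against control set 2). It held 12, 8 and 8 counts in the Commd10-deficient libraries and 1 and 3 in control set 2. The remaining rises were in Smim10l1 (3.01), the deubiquitinase Usp1 (2.82), the splicing factors Tra2a and Luc7l3 (2.41 each) and the vesicle GTPase Rab10 (2.39).

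Genes with the largest falls included a pair of selenoproteins of redox defence. Gpx4, the glutathione peroxidase that reduces lipid peroxides, on chromosome 10 from 80047166 to 80056439, fell from 75.3 ± 36.6 CPM (SD, n = 4) to 2.69 ± 4.67 CPM (SD, n = 3), with 1 count over the 3 Commd10-deficient libraries. Against the pooled counts of control set 2 that is a ratio of 0.0554 (95% counting interval 0.00135 to 0.337). The annotation holds 1 pseudogene named after Gpx4, and how shared reads were counted is not given. Txnrd2, the mitochondrial thioredoxin reductase, held 2 counts over the Commd10-deficient libraries, a ratio of 0.111 to control set 2 (0.0128 to 0.443), and its log2 fold change was -3.18 (SE 0.77). The lipid-binding protein gene Osbpl11 held 1 count, a ratio of 0.0389 (0.00096 to 0.231), and Arrb1, encoding beta-arrestin 1, held 2 counts, a ratio of 0.0686 (0.00805 to 0.264). Hes1, a Notch target, fell from 85.7 ± 48.3 to 14.1 ± 8.84 CPM (log2 fold change -2.67). Myl6, a myosin light chain, fell by 2.73 on the log2 scale and Sec13, a coat protein of vesicles leaving the endoplasmic reticulum, fell by 2.43. The others were Carkd (-2.69), Rab29 (-2.62), Guca1a (-2.62), Zfand2b (-2.57) and Tmem160 (-2.46). Exons of the opposite strand overlap those of Txnrd2, Cap1, Tmed5 and Rab10, and a gene on the same strand overlaps Smim10l1, so reads there cannot all be assigned with certainty.

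**Figure D2:**
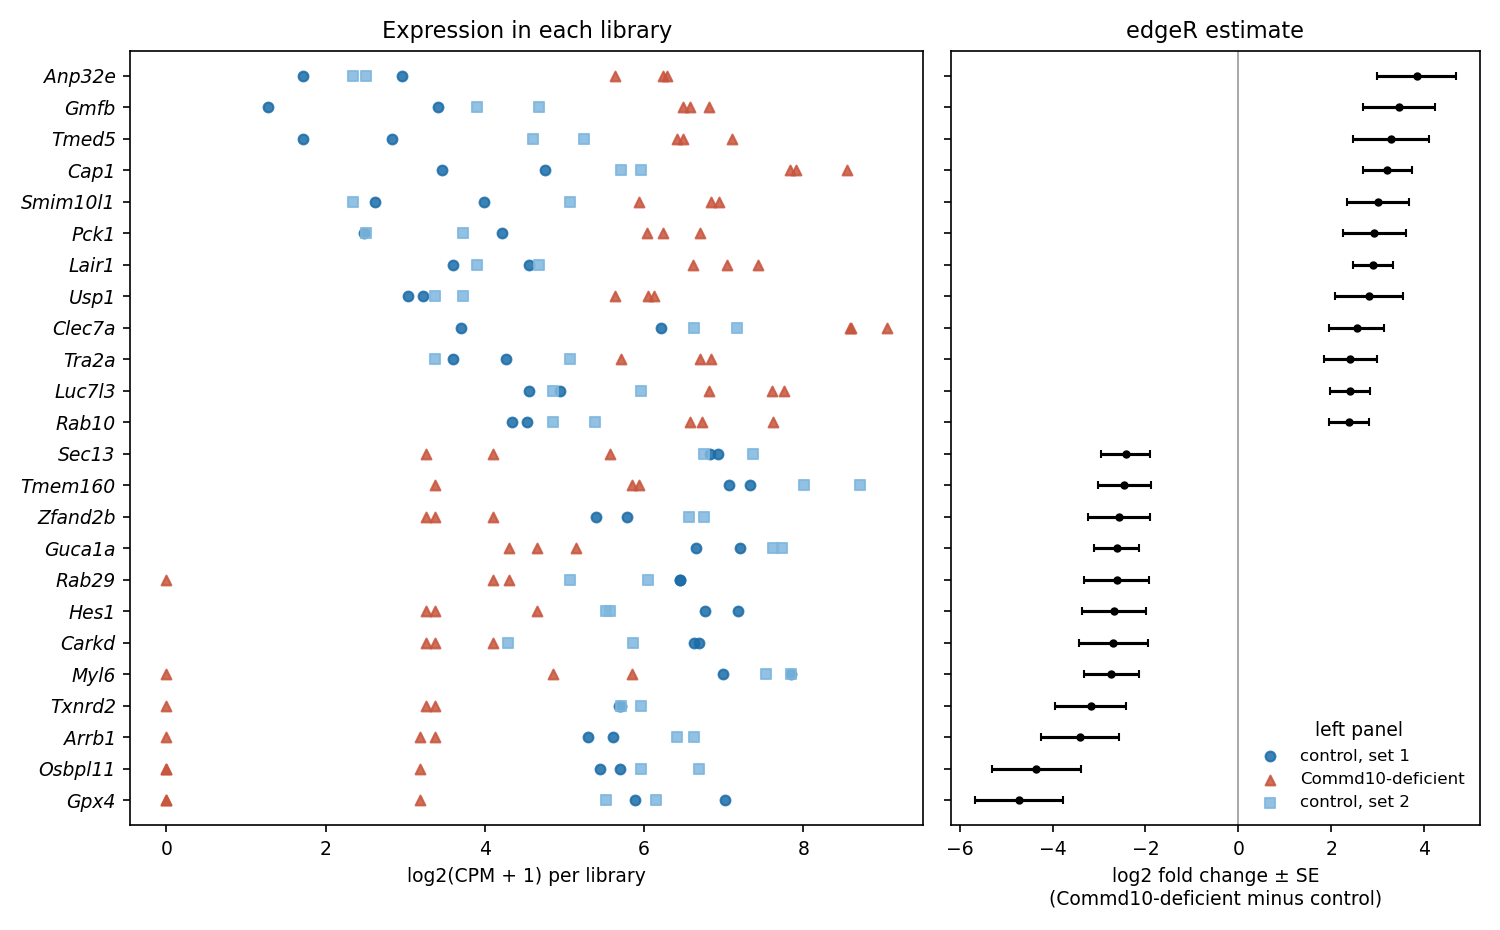
Genes with the largest changes between Commd10-deficient and control Kupffer cells. Left, log2(CPM + 1) in each of the 7 libraries, and right, the edgeR log2 fold change with its standard error, Commd10-deficient minus control. The 24 genes were chosen among those whose Commd10-deficient libraries lie outside the range of the 4 controls. In the fit to all controls Gpx4 has the largest fall (-4.73), with Osbpl11 the lower of the pair against control set 2 (-4.77 and -4.26).

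The count of 206 came from the edgeR quasi-likelihood test at an adjusted p under 0.05, and 825 genes had an unadjusted p under 0.05. Of the called genes, 204 showed no overlap between groups, as did 25% of all tested genes, against the 5.71% that chance gives for 3 against 4. That 5.71% holds only if any library could stand in for any other, which the difference between the control sets argues against. A shift of the Commd10-deficient libraries for any reason would raise the share. With control set 2 alone, the controls nearest in depth, 697 genes were called (345 higher, 352 lower) among fewer tested genes, and 576 (310 higher, 266 lower) with control set 1 alone. Control set 1 holds controls only, so a contrast within that depth was not possible. Of the 206 genes, 181 were tested against control set 2 alone and 176 of them were called in the same direction. Only 14 of the 24 genes with the largest changes could be tested there, and all 14 were called. With control set 1 alone 16 of the 24 were tested and 15 called. In the model with 3 levels, all 206 had the same sign against both control sets, and 178 passed the threshold against each. The 206 were selected from these same libraries and 204 showed no overlap, so shared signs and directions were nearly fixed by that selection. Against control set 2 in that model Gmfb, Tmed5, Usp1, Clec7a, Carkd, Hes1 and Rab29 did not pass. DESeq2 called 369 genes (212 higher, 157 lower), limma-voom 200 (166 higher, 34 lower) and edgeR with no filter 514 (211 higher, 303 lower). Limma-voom kept 141 of the 206 calls, and 12 of the 24 genes with the largest changes were no longer called there. Without Commd10-deficient replicate 1 or without replicate 2 edgeR called 0 genes (666 and 683 at an unadjusted p under 0.05), DESeq2 90 and 97 of the genes edgeR tested, and limma-voom 0 and 15. Without replicate 3 the counts were 60, 247 and 81. Replicates 1 and 2 were the Commd10-deficient pair that differed least from each other. With an offset for GC content and transcript length the count was 110, of which 85 were among the 206. In that fit Anp32e, Gmfb, Tmed5, Smim10l1, Usp1, Clec7a, Tra2a, Luc7l3, Carkd, Rab29, Zfand2b and Tmem160 were no longer called.

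Kupffer cell identity genes did not move in a shared direction. Of 27 tested members, 1 fell and 26 did not pass in edgeR, while DESeq2 called 3 and limma-voom 1. In edgeR 11 had an unadjusted p under 0.05, and adjusted over the list alone, 2 were higher and 2 lower. Fry for change in either direction gave the list an adjusted p of 0.0078. The gene that fell in edgeR was Marco, a scavenger receptor for bacteria and particles, on chromosome 1 from 120474538 to 120505024. Its level was 2036 ± 769 CPM in controls and 593 ± 141 CPM in Commd10-deficient cells (log2 fold change -1.78, SE 0.34), and -1.74 against control set 2. Clec4f, whose locus drives Cre, was at 12267 ± 1582 and 11576 ± 1463 CPM (-0.08, SE 0.23). The other genes of the sort gate, on which the cells were selected, had log2 fold changes of -0.20 for Timd4, 0.14 for Clec1b, 0.70 for Vsig4, 0.77 for Adgre1 and 0.88 for Ptprc, and 0 of the 6 tested passed in edgeR, DESeq2 or limma-voom (3 at an unadjusted p under 0.05, 3 higher adjusted over the list alone). Pcolce2 (-1.18), the hemoglobin scavenger receptor Cd163 (1.09) and the iron exporter Slc40a1 (1.99) did not pass in edgeR. Between control set 1 and control set 2 Slc40a1 was at -2.19 (adjusted p = 0.063).

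Among pan-macrophage genes, 1 of 16 tested fell (3 higher and 3 lower adjusted over the list alone). Tyrobp, the adaptor of many activating myeloid receptors, fell from 7203 ± 1855 to 2876 ± 652 CPM (log2 fold change -1.32, SE 0.28). Macrophage genes linked to a monocyte origin or to lipid handling had a median of 1.04 over 6 tested members. In this list Ms4a7 rose from 67.0 ± 5.57 to 211 ± 65.9 CPM (1.66, SE 0.33), and 3 were higher adjusted over the list alone. Cd36 (2.55) and Lpl (1.78), both of lipid uptake, did not pass over all genes; between the control sets they were at -2.24 (adjusted p = 0.046) and -1.69 (adjusted p = 0.067). Monocyte genes gave 0 calls among 6 tested with edgeR, DESeq2 and limma-voom (1 at an unadjusted p under 0.05, 0 adjusted over the list alone), and Clec12a was at 0.84. The MHC class II gene H2-Aa rose from 5547 ± 1280 to 13046 ± 1349 CPM (1.23, SE 0.25), the only edgeR call among 9 tested presentation genes; DESeq2 and limma-voom each called 3. Adjusted over the list alone 3 were higher, which include H2-Eb1 (0.85) and H2-DMa (0.86).

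Inflammasome and pyroptosis genes had 3 rises among 8 tested, the same 3 adjusted over the list alone. Il1b, the cytokine that caspase-1 processes, on chromosome 2 from 129364570 to 129371139, rose from 969 ± 56.7 to 1926 ± 16.1 CPM (log2 fold change 0.99, SE 0.23). The SD of 16.1 is smaller than counting error alone would give at this depth, so it understates the spread. Casp1 rose from 211 ± 96.1 to 678 ± 88.5 CPM (1.72, SE 0.40) and Casp4, the mouse caspase-11 gene, from 128 ± 67.9 to 412 ± 91.0 CPM (1.78, SE 0.42). Against control set 1 and control set 2 Casp4 was 2.55 and 1.15 higher, with the control sets apart by -1.40 (adjusted p = 0.0082), and Casp1 2.15 and 1.33 higher. As a set the list did not pass in camera (median 0.79, adjusted p = 0.126, and adjusted p = 0.800 with an estimated correlation), while fry gave an adjusted p of 0.00099. With the GC and length offset the edgeR log2 fold changes of Casp1 (1.14) and Casp4 (1.27) were no longer called. Of 10 tested apoptosis and p53 target genes, Casp8, the initiator caspase of death receptors, rose by 1.49 (SE 0.30), and with Cdkn1a (1.46) 2 were higher adjusted over the list alone.

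In the list of the COMMD complexes and their retriever and WASH partners, 1 of 14 tested genes rose and 1 fell, the same adjusted over the list alone. Vps35, the core subunit of the endosomal retromer, rose from 45.8 ± 5.92 to 175 ± 17.8 CPM (log2 fold change 1.97, SE 0.34). Commd4 fell from 146 ± 22.7 to 46.8 ± 19.6 CPM (-1.65, SE 0.41). Among 29 tested lysosome genes, the membrane protein gene Lamp2 rose by 1.14 (SE 0.28), and 2 were higher adjusted over the list alone. Autophagy genes gave 0 calls among 13 in edgeR, DESeq2 and limma-voom (1 at an unadjusted p under 0.05, 0 adjusted over the list alone). The endoplasmic reticulum stress genes Xbp1 (1.27, SE 0.26) and Hspa5 (1.30, SE 0.28) rose, 2 of 11 tested, and the same number passed adjusted over the list alone. With the GC and length offset Lamp2 was at 0.085 (adjusted p = 0.901), and Vps35 (1.25), Commd4 (-1.29) and Hspa5 (0.99) were not called either. Lamp2 was also not called with no filter, without control replicate 1 or without Commd10-deficient replicate 3. Exons of the opposite strand overlap those of Vps35.

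In the NF-kB list the adhesion molecule Icam1 fell by 1.46 (SE 0.33) and Il1b rose, 2 calls of 20 in all and the same adjusted over the list alone. The median of the NF-kB list was -0.30 against control set 1 (camera adjusted p = 0.405) and 0.83 against control set 2 (0.0448, and adjusted p = 0.526 with an estimated correlation). Between control set 1 and control set 2 it was 1.10 (3.5e-05, and adjusted p = 0.161 with an estimated correlation), and with control set 2 alone in the fit 0 lists passed in camera (lowest adjusted p = 0.0895, 4 lists at an unadjusted p under 0.05). Oasl2 (1.45, SE 0.37) was the 1 call among 17 interferon response genes, also adjusted over the list alone. Of 20 dissociation and immediate early genes only Klf2, a shear-responsive transcription factor, passed, falling from 531 ± 245 to 118 ± 35.6 CPM (-2.19, SE 0.42), and 1 was lower adjusted over the list alone. The median of this list was -0.77 against control set 1 and 0.32 against control set 2, and 1.26 between control set 1 and control set 2. Ferritin heavy chain Fth1 was the 1 call among 16 iron and heme genes (-0.81, SE 0.23), where 2 were higher and 2 lower adjusted over the list alone. With the GC and length offset Oasl2 (1.27) and Fth1 (-0.53) were not called. Hes1 was the 1 call of 7 BMP, TGF-beta and Notch genes, and Marco the 1 call of 12 efferocytosis and scavenger genes. Adjusted over the lists alone, 1 was lower in the former, and 2 were higher and 1 lower in the latter. Between control set 1 and control set 2 Hes1 was at 1.45 (edgeR adjusted p = 0.023). The median of its list was 0.93 there (camera adjusted p = 0.0044, and adjusted p = 0.274 with an estimated correlation). Complement genes gave 0 calls of 10 in edgeR and 2 each in DESeq2 and limma-voom (4 at an unadjusted p under 0.05, 2 higher and 1 lower adjusted over the list alone), with C1qc at 0.72 and C3 at -1.34. Of 10 tested LXR targets edgeR and DESeq2 called 0 and limma-voom 1 (1 at an unadjusted p under 0.05, 0 adjusted over the list alone). The 5 tested cell cycle genes and 1 of cholesterol synthesis had 0 at an unadjusted p under 0.05 in edgeR and 0 calls in each tool, also adjusted over the lists alone.

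Markers of liver cells outside the myeloid lists gave a single call. Serpina3k, a hepatocyte serpin, rose from 294 ± 67.2 to 630 ± 177 CPM (log2 fold change 1.08, SE 0.30), the 1 call of 13 hepatocyte genes, with 2 higher adjusted over the list alone; an overlapping family member, Serpina3m, shares its strand. Other hepatocyte genes lay on both sides of 0, with Mup3 at 0.89, Apoa2 at -0.96 and Ttr at -0.80, and Serpina3k (0.94) was not called with the GC and length offset. The list took 0.610% and 0.564% of all counts in control set 1, 0.906% and 0.862% in control set 2, and 0.776%, 0.781% and 0.726% in the Commd10-deficient libraries. Between control set 1 and control set 2 its median was -0.81 (camera adjusted p = 0.0265, and adjusted p = 0.283 with an estimated correlation). Sinusoidal endothelial genes gave 0 calls of 5 in edgeR, DESeq2 and limma-voom (1 at an unadjusted p under 0.05, 0 adjusted over the list alone), with Stab2 at 0.08. The neutrophil list had 2 tested members, and the stellate cell, B cell, dendritic cell and platelet lists 1 each, with 0 calls in the 3 tools, 0 at an unadjusted p under 0.05 in edgeR and 0 adjusted over the lists alone. The T and NK cell and mitochondrial lists had 0 tested members. Of the 23 lists with at least 3 tested members, 0 passed in camera; 3 had an unadjusted p under 0.05, and 1 with an estimated correlation. Fry called 1 list for direction, inflammasome and pyroptosis, and 14 for change in either direction. Median, mean and test differed in sign for the monocyte, lysosome, efferocytosis, complement and BMP lists.

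**Figure D3:**
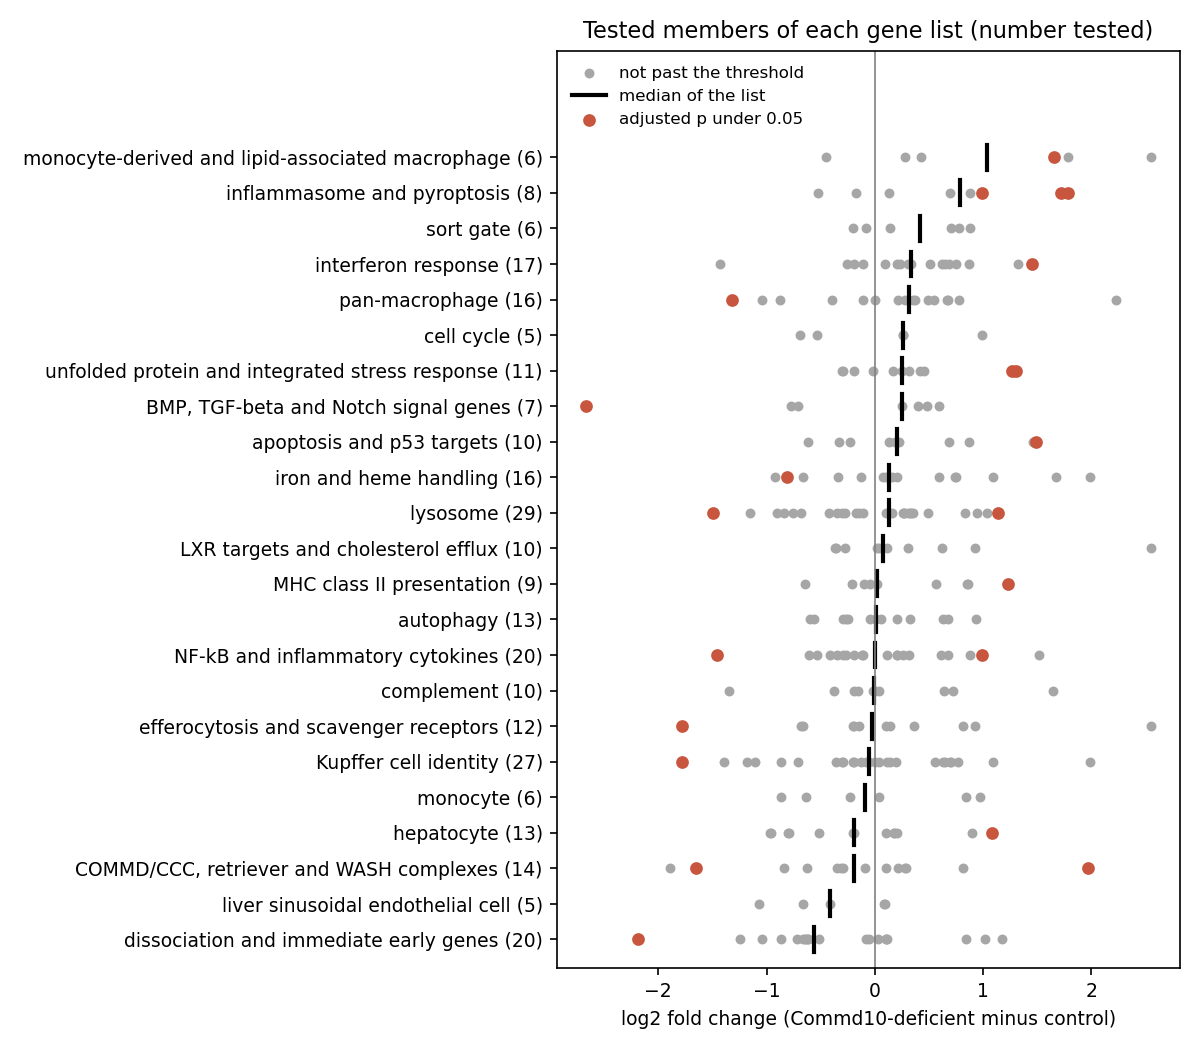
Members of each gene list between Commd10-deficient and control Kupffer cells. Each point is the log2 fold change of a tested gene, coloured where its adjusted p is under 0.05, and each black bar is the median of the list, with the number of tested genes in brackets. List medians run from -0.56 to 1.04 and most lists hold members on both sides of 0.

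Control set 1 and control set 2 differed from each other in 637 of the 3412 genes, 266 higher and 371 lower in control set 1, although the labels give them the same genotype, sex and age. In the same model with 3 levels, Commd10-deficient cells differed from control set 1 in 658 genes and from control set 2 in 650. Each genotype contrast thus held about as many genes as the contrast between the controls. Against this background, 129 genes were higher in Commd10-deficient cells than in each control set and 116 were lower than in each, with 6 in opposite directions. Independent lists of those lengths would share 34.4 and 27.2, and simulated libraries with no effect gave a mean of 0.05 each way. Both real contrasts use the same Commd10-deficient libraries, and the simulation held no shift between groups of libraries like that between the control sets. Any shift of the Commd10-deficient libraries would enter both contrasts, so these values are no background for the 129 and 116. Vps35 was 2.08 higher than control set 1 and 1.80 higher than control set 2, Il1b 0.92 and 1.06, and Xbp1 1.21 and 1.33. Marco (-1.82 and -1.74) and Tyrobp (-0.98 and -1.60) were lower than each. With control replicate 1, 2, 3 or 4 left out, the contrast of the control sets called 450, 366, 338 and 157 genes; a set then holds 1 library, which is assumed to vary like the other groups.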

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

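The tests with the GC and length offset and with thinned libraries were chosen only after the result was seen. The prediction for the other splits of the libraries was written before that test was run. Over 97 groups of 4 control libraries, 3 held a library far from the other 3, and chance gives that in about 1 in 20 groups. Txnrd2 was at 61.4 CPM in control replicate 4 against 50.4 to 51.6 CPM in the other controls. H2-Aa was at 3627 CPM in control replicate 1 against 6164 to 6200 CPM. Mrc1 was at 448 CPM in control replicate 3 against 371 to 378 CPM.

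The 206 genes called between Commd10-deficient and control Kupffer cells leaned toward low GC content and long transcripts among the rises (medians 44.8% and 2782 nt) and the reverse among the falls (54.5% and 1159 nt). Such a lean could come from library preparation. After an offset for GC content and length the genes kept a median of 81.6% of their log2 fold change (quartiles 68.1% and 95.3%). Only 85 of the 206 stayed called. The offset takes out only the average trend with GC content and length, and 202 of the 206 were called at 2-fold or more. The share kept after the offset therefore cannot decide whether library preparation made the changes. After thinning to equal depth the 159 genes still testable kept a median of 99.8%, and 157 stayed called. Of the 24 genes with the largest changes only 7 could be tested so. Thinning by a fixed fraction per library keeps the expected fold change whatever its cause, so the share kept cannot decide whether depth made the changes. Of the 35 splits of the 7 libraries into 3 and 4, only the real split called as many genes (206, highest other 1), so chance can be excluded only as far as the libraries are exchangeable, which the difference between the control sets argues against; a genotype effect remains a hypothesis, since Cre goes with the genotype and batch was not recorded, and neither was tested.

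Between control set 1 and control set 2, 637 genes differed. After thinning, these genes kept a median of 97.8% of their log2 fold change (quartiles 91.4% and 105%). At the lower depth 240 stayed called, so those calls do not need unequal counts. Thinning by a fixed fraction per library keeps the expected fold change whatever its cause. The share kept therefore cannot decide whether the depth difference made the changes. After the GC and length offset they kept a median of 95.3%, and 544 stayed called. Day and handling of the cells were not recorded and stay open.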

How the results depend on the processing

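The fits with the GC and length offset and with thinned libraries were chosen only after the results were seen. All 206 genes called between genotypes kept their sign wherever they were tested under each tool, filter, control set and left-out library run. These genes were selected from the same libraries and 204 of them showed no overlap between groups, so their signs were nearly fixed in advance. The count stayed within 1.5 times of 206 with DESeq2 size factors (221), the stricter filter (272), no robust shrinkage (214), a minimum log2 fold change of 1 (202) and thinning (218). It was 369 (212 higher, 157 lower) with the DESeq2 Wald test, 514 (211 and 303) with no filter, 576 (310 and 266) with control set 1 only, 697 (345 and 352) with control set 2 only, 687 (384 and 303) with the 3-level model, 110 (64 and 46) with the GC and length offset, and 493 (245 and 248) with control set 2 only and the offset; limma-voom called 34 lower genes. The cause was not tested, except that the fits with a single control set hold fewer samples. Gene lists past the threshold numbered 1 with the stricter filter (at least 10 counts in at least 3 samples), 1 with the 3-level model and 1 with fry, directional (inflammasome and pyroptosis in each), and 1 with control set 1 only (dissociation and immediate early genes). The cause was not tested. Against control set 1 in the 3-level model, camera gave the dissociation list an adjusted p of 0.0218, and 0.615 with an estimated correlation. Genes between control set 1 and control set 2 numbered 302 when thinned to equal depth, where fewer counts are left.

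With each library left out in turn, the ranges were 0 to 276 for Commd10-deficient against control genes (0 without Commd10_deficient replicate 1 or 2, 60 without replicate 3), 0 to 161 for genes higher, 0 to 135 for genes lower, and 157 to 450 for control set 1 against control set 2 genes. Where edgeR called 0, 666 and 683 genes had an unadjusted p under 0.05, DESeq2 called 90 and 97 and limma-voom 0 and 15. Commd10 was 0.0037 and Clec4f 0.017 with control set 2 only. Clec1b was -0.11 with no filter on low counts and -0.23 with control set 1 only, and ran from -0.084 to 0.28 with a library left out. Stab2 was -0.15 and -0.12 in those fits and ran from -0.13 to 0.22. Timd4 was 0.27 with control set 1 only and ran from -0.40 to 0.022. None of these genes passed the threshold in the reported fit, and the cause was not tested. Over the single genes followed through the alternatives, 1228 values kept sign and side of the threshold, 233 lost the call, 183 gained it and 11 changed sign. No paired analysis was possible because the numbers in the sample titles are not shared between the groups. Depth limits genes below 28.4 CPM in the shallowest library, and 7138 genes were not tested.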

Other observations

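The genes and lists in this part, and the tests of the ribosomal protein and selenoprotein genes, were chosen after their values were seen. In Commd10-deficient Kupffer cells the MHC class I genes B2m (log2 fold change 1.10) and H2-T23 (1.52) rose, as did the endotoxin receptor Tlr4 (1.69), the adhesion molecule Vcam1 (1.83), Nrp1 (2.03) and App (1.52). With the GC and length offset H2-T23, Vcam1, Nrp1 and App were still called, and B2m and Tlr4 were not. Lsg1, a ribosome assembly GTPase, held 0 counts in all 3 Commd10-deficient libraries and 135, 147, 23 and 6 in the controls, at least 4.35-fold below control set 1 and 6.71-fold below control set 2 over pooled counts, with a floor of 3 counts over the 3 Commd10-deficient libraries together (2.59-fold without control replicate 3); it was not tested. Altogether, 10 genes held 0 counts in control set 2 where 20 or more were expected from the Commd10-deficient libraries, and 1 gene, Lsg1, the reverse. Mup8 held 1069 and 1130 counts in control set 1 and 0 in the other 5 libraries.

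Ribosomal protein genes were lower in Commd10-deficient cells, with 64 of 70 below 0, 12 of them called (Rps20 at -2.17) and a median of -0.81. The median was -0.38 against control set 1 and -1.12 against control set 2, and the control sets differed by -0.73 between themselves. These genes took 8.42%, 8.27%, 12.6% and 12.4% of counts in controls 1 to 4 and 5.44%, 5.35% and 7.98% in the Commd10-deficient libraries. Short, GC-rich transcripts could fall through library preparation. After the GC and length offset 65.6% of the median fall remained (quartiles -0.87 and -0.17), and 5 genes of the list were called lower in that fit. The average trend that the offset fits thus does not account for all of the fall, while other effects of library preparation stay open. Camera gave a p of 2.4e-14 at the preset correlation and 0.133 with an estimated correlation, so the shift is not separable from genes that vary together. Of 72 respiratory chain genes 7 fell, among them Cox4i1 (-1.63) and Ndufb10 (-2.09), and Sdha rose (1.23; not called in 9 of 19 alternatives, the offset among them), with a median of -0.34. Random lists matched for GC content and length had a median of -0.25, and 14.7% of them lay at or below this list. Among random lists matched for expression instead, 0.78% lay at or below this list. After the offset its median was -0.18, with 3 called lower. Camera gave this list a p of 2.3e-04, and 0.242 with an estimated correlation.

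Gpx4 and Txnrd2 are both selenoproteins, and the hypothesis tested was that selenoprotein messages may be lost together in Commd10-deficient cells. The other 12 tested selenoprotein genes had a median log2 fold change of -0.023 (quartiles -0.53 and 0.31) and 0 were called by edgeR, so the test gave no loss of the group. Secisbp2l, a paralog of the selenocysteine insertion factor gene Secisbp2, rose by 2.23 and was not called with the offset.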
